A study of Mus musculus with 6 samples.

How the data were processed

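Bulk RNA-seq was made from natural killer (NK) cells of mouse spleen. Per the labels' protocols, splenocytes were enriched with DX5 magnetic beads and sorted as CD49b-positive, CD3e-negative cells, 1 mouse gave 1 library, and libraries were made with the SMART-seq HT kit. The 6 libraries fall into 2 groups of 3: wild type (WT 1, 2 and 3) and mice in which serines 303 and 307 of heat shock factor 1 (HSF1) are replaced by alanine (S303/7A 5, 6 and 7). The replicate numbers are not shared between the groups, so no pairing was possible, and the labels give no batch. Other parts of the study, on single cells of tumours and on open chromatin, were not used here.

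Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and DESeq2 were used, with the mouse build GRCm38 (mm10). Versions, the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited a table of raw counts per gene for 55291 gene names, of which 21224 had no count in any library, and a table of normalized signal per gene. Dividing the deposited raw counts by the deposited normalized signal gave 1 factor per library, from 0.817 to 1.40, equal to the median-of-ratios size factors computed from the raw counts. Multiplying back recovered the whole count, within 0.01, for 100% of values in all libraries. The raw counts were therefore the only values tested, and the count test on the recovered reads is the same test. No row named anything other than a gene. Totals were 62667303, 53845572 and 72736406 counts in WT 1, 2 and 3 and 43189163, 43676820 and 47248039 in S303/7A 5, 6 and 7, so depth differed with genotype. The labels give 1 mouse per library, and all 6 were counted as separate replicates on that ground. Library pairs within groups had a chi-square per gene from 30.5 to 97.9, so no pair had counts equal within sampling noise, as 1 library deposited again would, but repeat preparations of 1 mouse would differ by more than that noise too.

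Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr (minimum count 10, minimum total 15), which left 16480 genes, TMM factors were computed, and the quasi-likelihood test (not robust) compared S303/7A with WT. Benjamini-Hochberg adjustment was over the genes tested, with a threshold of 0.05, and a gene that passed is described as called, higher or lower. Standard errors of log2 folds are Wald-type, from the same fit. CPM values are TMM-scaled and given as mean ± SD over 3 libraries. Counting intervals and floors (3 counts over a group) cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values of single genes rest on the spread between 3 mice per genotype. Fisher's exact tests and the random sets take genes as units, so their p-values do not measure spread between mice. Camera sets the genes of a list against the other genes, so its p-values rest on the spread between genes as well.

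Before the data were examined, the test, the alternatives, 42 gene lists (28 pathway, 11 cell type and 3 sample check lists) and a rule for the genes to be named were fixed. The rule takes Hsf1, up to 12 genes per direction with the largest fold among called genes with mean log2 CPM of at least 2 and no overlap between the groups, leaving out predicted loci and pseudogenes, up to 4 called members per list, and 18 heat shock and NK genes whatever their values. Genes named outside it were chosen after their values were seen, also where this is not repeated beside them, except members of the sample check lists. The 39 pathway and cell type lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 (limma 3.58.1), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives. Fry's mixed test, which asks whether members change in either direction, is given by name for receptor and maturation lists. It does not set them against other genes. The sample check lists were given as values.

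On simulated counts with the means and library sizes of these 16480 genes and 200 changed genes, the test recovered 5 of 50 genes at 1.5-fold, 20 of 50 at 2-fold, 42 of 50 at 4-fold and 45 of 50 at 8-fold, with 7 false calls. The changed genes were not drawn from those of lowest mean CPM, so recovery over all tested genes may be lower. DESeq2 made 60 false calls and limma 5 in the same simulation. None of 40 unchanged lists was called and the shifted list was. Simulated genes were drawn independently of each other, so this does not check the list test for genes that vary together. In the real data the estimated correlation within a list reached 0.816. The true value lay within 2 SE for 91.5% of the changed genes.

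Positions are from GENCODE release 21 for mouse and, for names it lacks, RefSeq annotation of GRCm38.p6, both on the authors' build. Of the 55291 names, 54265 had a position. Called genes within 10 Mb of Hsf1 were compared with the rest of the genome by Fisher's exact test, 2-sided. The number of called genes with another called gene within 5 Mb was set against 10000 random sets of tested genes. The longest transcript of each called gene was searched against all transcripts with BLAST 2.17.0, and another gene that does not overlap it with at least 95% identity over at least 200 bases was taken as a near-identical copy. How reads that fit several genes were counted is not given in the sources used here, so genes with such a copy are uncertain, as are overlapping and antisense genes.

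Alternatives fixed in advance were edgeR's RLE factors, library totals only, no low-count filter, CPM of at least 5 in at least 3 libraries, leaving out each library in turn, DESeq2 1.42.0, limma-voom with sample weights, robust quasi-likelihood and a threshold of 0.1. Added after seeing the data were thinning of every library to the smallest total, 1 surrogate variable from svaseq (sva 3.50.0) as a covariate, the level of the heat shock list without Hspa1a and Hspa1b, and the count of called neighbours, at 5 Mb and at 1 and 2 Mb. A check of depth against the spread within genotypes was left out because it ordered libraries by a measured gene.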

Results

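Transcripts of splenic NK cells were counted in 6 mice kept at steady state, 3 of them wild type and 3 carrying the S303/7A form of HSF1, the transcription factor that drives the heat shock response. The series text calls the S303/7A mice HSF1-enhanced, and the comparison asks how their resting NK cells differ from those of wild-type mice. Total counts ranged from 53845572 to 72736406 in WT and from 43189163 to 47248039 in S303/7A. The first principal component, with 28.4% of the variance, separated the genotypes, and Spearman correlations of log2 CPM ranged from 0.972 to 0.984 within and from 0.967 to 0.976 between genotypes. The second component, with 24.1%, separated libraries of the same genotype.

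Hsf1 itself (chromosome 15, 76477422 to 76501913, GRCm38) was measured at 83.2, 104 and 108 CPM in the WT libraries and at 67.0, 42.2 and 76.9 CPM in the S303/7A libraries. Its log2 fold of S303/7A over WT was -0.67 ± 0.22 (SE), with an adjusted p of 0.386 in edgeR's quasi-likelihood test, so it did not pass. The mutations change 2 codons, so the transcript level does not check the labels.

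Of 16480 genes tested, 60 differed between the genotypes, 22 of them higher and 38 lower in S303/7A, and 58 by at least 1.5-fold. At an unadjusted p under 0.05 there were 1595 genes. Among the higher genes with a known product were Kcnj8, a potassium channel subunit (0.223 ± 0.203 CPM in WT and 38.5 ± 8.16 in S303/7A, SD, n = 3 each), Il15, the cytokine that NK cells depend on (3.93 ± 1.33 and 15.7 ± 0.471 CPM), Pik3ip1, an inhibitor of phosphoinositide 3-kinase (14.5 ± 1.09 and 59.0 ± 13.5 CPM), Lgals3, a galectin (50.7 ± 1.49 and 202 ± 67.3 CPM) and Supt16, a histone chaperone subunit (49.3 ± 3.09 and 195 ± 51.7 CPM). Among the lower genes were Ada, adenosine deaminase (61.9 ± 4.68 and 14.3 ± 1.34 CPM), and Hk2, a hexokinase (14.1 ± 0.556 and 5.69 ± 0.822 CPM).

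The log2 fold was 7.38 ± 0.58 (SE) for Kcnj8, 2.00 ± 0.25 for Il15, 2.02 ± 0.17 for Pik3ip1, 1.99 ± 0.23 for Lgals3 and 1.99 ± 0.18 for Supt16. It was -2.11 ± 0.12 for Ada and -1.31 ± 0.17 for Hk2. Their adjusted p values ranged from 0.00168 for Ada to 0.0453 for Il15 in edgeR's quasi-likelihood test. Smaller increases were fitted for Gnpda1 (1.17 ± 0.12), Dhcr7, the last enzyme of cholesterol synthesis (1.16 ± 0.12), Mri1 (1.02 ± 0.10) and Ggh (0.88 ± 0.12). Lyplal1 fell by 3.50 ± 0.43, Rab44 by 1.93 ± 0.23 and Eno1b by 1.37 ± 0.14 on the log2 scale. Eno1b shares 99.5% of 1652 bases with the glycolytic enolase gene Eno1, whose own log2 fold was 0.34, and is uncertain for that reason, as is Gnpda1, which shares 99.1% of 753 bases with Gm8615.

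Itln1, which encodes an intestinal lectin, had 5596 counts over the WT libraries and 2 over the S303/7A libraries, a ratio of 1944 with an exact 95% counting interval from 538 to 16060. The zinc finger genes Zfp979 and Zfp990 on chromosome 4 had 2516 and 1531 counts in WT against 11 and 13 in S303/7A, ratios of 159 (interval 88.7 to 319) and 81.8 (47.7 to 154). Both have a near-identical copy. Leaving out 1 library reduced the 60 calls to 27 without WT 1, 5 without WT 2, 21 without WT 3, 31 without S303/7A 5 and 30 without S303/7A 7, while 57 were made without S303/7A 6, 24 of them shared. In that last fit 38 genes were higher and 19 lower, the opposite balance. Of the 29 called genes named here, Ada, Itln1 and Zfp990 passed in all 6 of these fits and 7 passed in none (Ggh, Hk2, Lyplal1, Ms4a2, Rab44, Slamf1 and Vwf). Kcnj8 passed in 5, Pik3ip1, Supt16, Mri1 and Zfp979 in 3, Dhcr7 and Eno1b in 2, and Il15, Lgals3 and Gnpda1 in 1. Limma-voom did not call Itln1 (adjusted p 0.0779), Lgals3 (0.0643), Ggh (0.0516), Lyplal1 (0.0950) or Rab44 (0.0793). After thinning to equal totals Il15 (0.0539) and Ggh (0.0505) were not called. Ggh was not called with library totals either (0.0517).

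**Figure D1:**
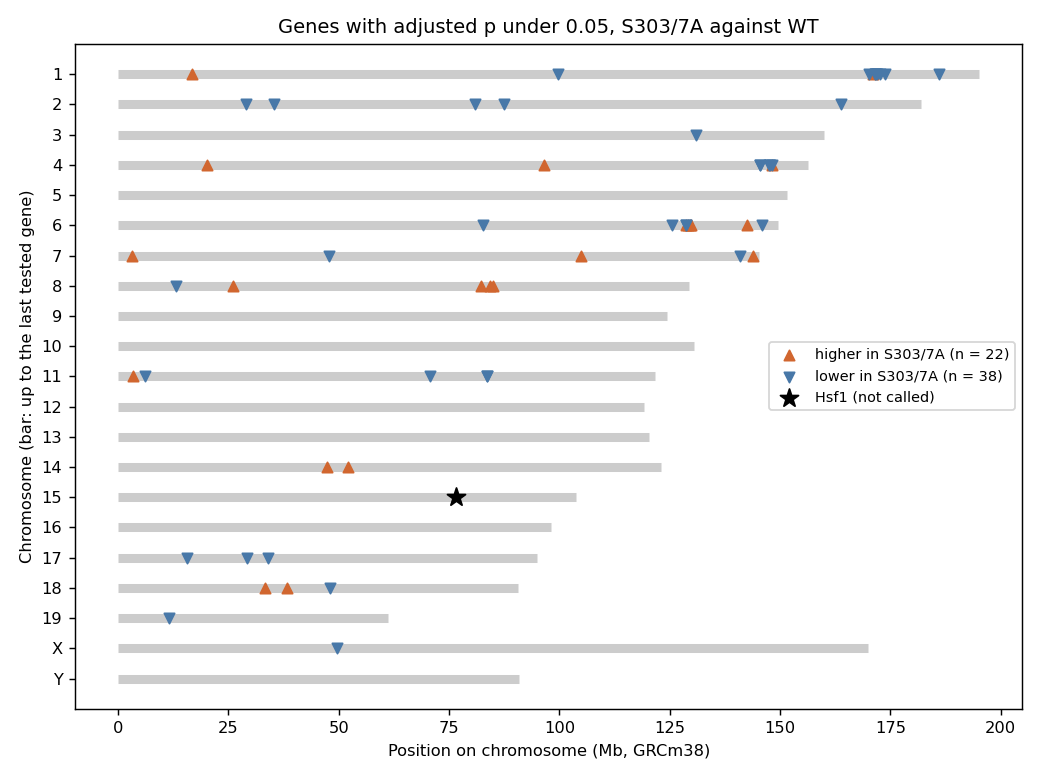
Positions of the 60 genes that differed between S303/7A and WT (x axis, Mb on GRCm38; y axis, chromosome). Upward triangles are the 22 higher and downward triangles the 38 lower genes, the star is Hsf1, and groups of 8, 6 and 7 called genes stand close together on chromosomes 1, 4 and 6.

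Receptor genes of NK cells were among those that differed, in both directions. The called ones named in this paragraph all lie in the close groups of called genes on chromosomes 1 and 6 described below. Blocks of another strain background, a candidate explanation for those groups, were not separated from an effect of the mutations. In the NK gene complex on chromosome 6, Klra17 (log2 fold 2.52 ± 0.32, SE), Klrc3 (1.49 ± 0.13) and Klrb1a (0.70 ± 0.08) were higher in S303/7A, and Klrb1 (-1.49 ± 0.13) and Klrb1c, the NK1.1 antigen gene (-0.54 ± 0.07), were lower. Klrb1c went from 2463 ± 204 to 1690 ± 58.5 CPM (SD, n = 3), with an adjusted p of 0.0454 in edgeR's quasi-likelihood test. On chromosome 1, Slamf1 (-2.09 ± 0.28), Slamf6 (-1.29 ± 0.14), Fcrl6 (-1.76 ± 0.16) and the adaptor gene Sh2d1b2 (-1.92 ± 0.25) were lower, and Fcgr2b, the inhibitory Fc receptor gene, was higher (1.65 ± 0.22). Klrk1, which encodes NKG2D, was measured at 1432 ± 66.2 and 2119 ± 236 CPM, a log2 fold of 0.57 ± 0.09 that missed the threshold with an adjusted p of 0.0700 and passed in DESeq2 (2.3e-05), without the low-count filter (0.00524) and without S303/7A 6 (0.0144). Of the 6 fits that each left out 1 library, Klrb1 and Klrc3 passed in 5, Fcrl6 in 3, Klrb1c, Klra17, Klrb1a, Slamf6, Sh2d1b2 and Fcgr2b in 1 each, and Slamf1 in 0. Limma-voom did not call Klra17 (adjusted p 0.0712), Slamf1 (0.104) or Sh2d1b2 (0.0516). After thinning Klra17 (0.0505), Fcgr2b (0.0505) and Slamf1 (0.0511) were not called.

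Of 28 tested Klr genes in the stretch from 128609227 to 130386874 on chromosome 6, 4 were higher, 2 lower and 22 not called, and 21 had an unadjusted p under 0.05. In the list of activating receptors and adaptors, 1 of 27 rose and 3 fell (3 and 3 adjusted over the list alone), and the list was not called (adjusted p 0.824, camera). Camera looks for a shift in 1 direction, while fry's mixed test, which allows both, gave that list an adjusted p of 0.000751. In the Ly49 family list 1 of 13 rose (3 rose and 2 fell adjusted over the list alone), and the list was not called (adjusted p 0.353), except without S303/7A 6 (0.00497). That library lay near the WT level for several Ly49 genes, chosen after their values were seen and none of them called. Klra1 was at 572, 216 and 528 CPM in S303/7A 5, 6 and 7 and at 206 to 261 CPM in WT. Klra7 was at 334, 805 and 328 CPM against 873 to 948, and Klra14-ps at 31.8, 7.38 and 29.7 CPM against 6.30 to 8.61. This was not limited to Ly49 genes. H2-Q4 was at 73.52, 15.52 and 71.68 CPM against 15.33 to 16.85, and Glo1 at 138.7, 51.42 and 139.9 against 45.6 to 47.45. Both were uncalled and chosen after their values were seen. The genotype alone does not give such differences between S303/7A libraries, and their cause was not tested. Of 23 inhibitory and checkpoint receptors 0 were called in edgeR's quasi-likelihood test and 5 had an unadjusted p under 0.05, with 2 lower adjusted over the list alone (Lilrb4a and Klrb1b, named after their values were seen), and the list was not called (adjusted p 0.225, camera) but was called lower without WT 3 (0.0106). Fry's mixed test gave an adjusted p of 0.00235 for the inhibitory list and 0.0623 for the Ly49 list. Klrc3 shares 96.2% of 715 bases with Klrc2, Fcgr2b 96.3% of 512 bases with Fcgr3, and Slamf1 96.5% of 200 bases with A430103D13Rik, so their counts are uncertain.

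**Figure D2:**
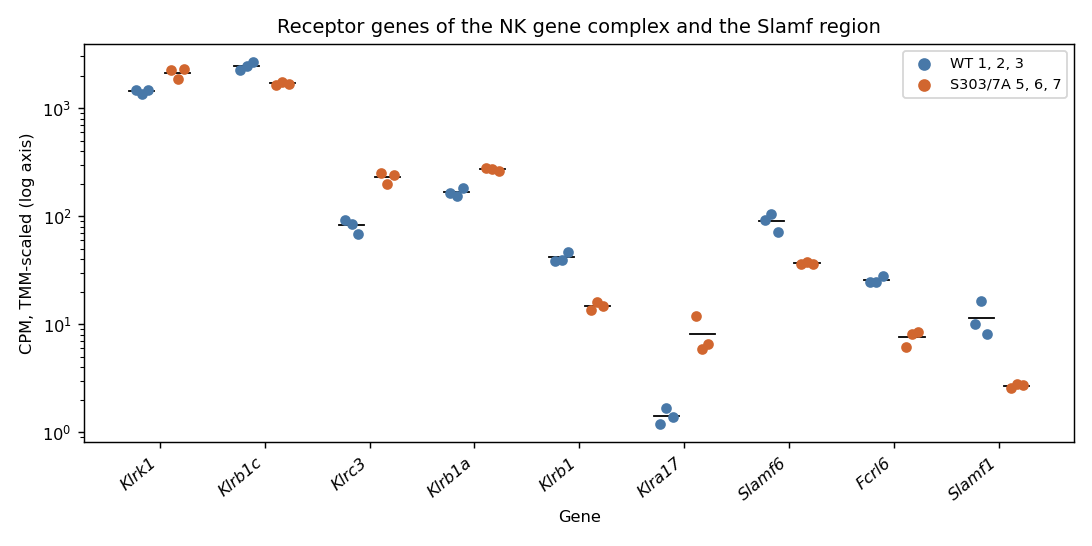
Expression of 9 receptor genes (y axis, TMM-scaled CPM on a log axis), 1 point per library and a line at the group mean, WT in blue and S303/7A in orange. The groups do not overlap for these genes, among them Klrk1, which did not pass the test.

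The effector genes Prf1, Gzma, Gzmb and Ifng and the maturation genes Itgam, Cd27 and Klrg1 did not pass the test. Prf1 (perforin) was at 2350 ± 310 CPM in WT and 2529 ± 174 in S303/7A, Gzma at 5579 ± 1405 and 5295 ± 568, Gzmb at 695 ± 190 and 562 ± 47.2, and Ifng at 45.2 ± 1.17 and 37.2 ± 5.98 (SD, n = 3). Log2 folds were 0.14 ± 0.06 (SE) for Ncr1, 0.14 ± 0.08 for the transcription factor gene Tbx21, 0.17 ± 0.12 for Itgam, 0.27 ± 0.13 for Cd27 and 0.21 ± 0.14 for Klrg1. Eomes, a transcription factor of NK cell identity, was at 476, 316 and 148 CPM in WT and 180, 140 and 717 CPM in S303/7A, a spread within each genotype far above the difference between them (log2 fold 0.14 ± 0.67). None of the 22 tested cytotoxic effectors or 32 NK transcription factors was called in edgeR's quasi-likelihood test, where 3 and 1 had an unadjusted p under 0.05. In the mature NK list 1 of 25 rose, Kcnj8 (3 rose and 1 fell adjusted over the list alone), and the immature list had 0 of 22. Of the 25 log2 folds of the mature list 13 were above 0 and 12 below, with a median of 0.00036. Their mean was 0.34, raised by Kcnj8 at 7.38. Camera called neither list (adjusted p 0.134 and 0.225), but the mature list without WT 3 (4.7e-07) and the immature list without WT 1 (0.0380), both higher. WT 3 had the highest mean log2 CPM of the mature list in WT (7.56, against 7.05 and 7.21), so leaving it out lowers the WT level. Fry's mixed test gave an adjusted p of 1.55e-05 for the mature list and 0.1115 for the immature list.

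The heat shock list was not called. Of 28 tested members of the list of heat shock response and HSF1 targets, 0 were called and 6 had an unadjusted p under 0.05, with 2 lower adjusted over the list alone, Hspa1b and Hsp90ab1, the latter named after its value was seen. The mean log2 CPM of the list was lower in S303/7A by more than 3 SE, with a difference of -0.18 ± 0.055 (SE) and no overlap between the libraries (6.19 to 6.33 in WT and 6.02 to 6.13 in S303/7A), which chance gives in 10% of cases with 3 against 3. Hspa1a and Hspa1b carried this difference: without that pair it was 0.03 ± 0.05 for the other 26 genes, with overlap, in a value added after the data were seen. By gene, 15 of the 28 log2 folds were above 0, their median was 0.01 and their mean -0.26, the test pointed down, and the adjusted p was 0.475 (camera) and 0.938 with an estimated correlation. Without WT 2 the list was called lower, with an adjusted p of 0.0278 in camera.

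Hspa1a and Hspa1b, the stress-inducible HSP70 genes, were at 1.76, 15.1 and 0.952 CPM and at 13.0, 89.3 and 10.9 CPM in WT 1, 2 and 3, against 0.420, 0.626 and 0.407 and 1.82, 3.02 and 2.08 CPM in S303/7A 5, 6 and 7. Their log2 folds were -3.61 ± 1.00 and -4.03 ± 0.80 (SE), with adjusted p of 0.331 and 0.181 in edgeR's quasi-likelihood test. DESeq2 called both (0.0011 and 0.00188), and Hspa1b was called without the low-count filter (0.0101). WT 2, with the highest values of both, also had the highest Fos (29.3 CPM, against 8.17 and 6.95 in the other WT libraries) and Jun (189, against 46.8 and 38.1) but not the highest Egr1 (49.7, against 55.4 and 38.4), all chosen after their values were seen. Fos (4.9 to 5.5 CPM) and Jun (17.75 to 34.23) were lower in every S303/7A library than in any WT library, as the pair was, though neither was called. Egr1 (37.6 to 44.7 CPM in S303/7A) overlapped between the genotypes. The pair shares 99.2% of 2201 bases, so reads between them are uncertain. Other chaperone genes had log2 folds of 0.33 ± 0.20 (Hsph1), 0.16 ± 0.14 (Dnajb1), -0.38 ± 0.14 (Hsp90aa1), -0.18 ± 0.10 (Hspa8) and 0.07 ± 0.15 (Bag3), none past the threshold.

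**Figure D3:**
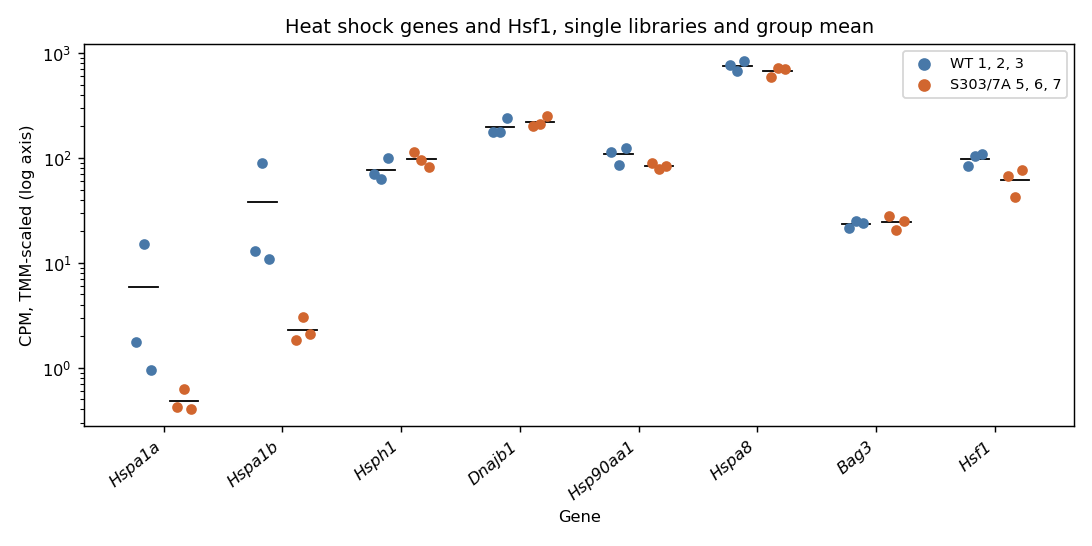
Expression of 7 heat shock genes and Hsf1 (y axis, TMM-scaled CPM on a log axis), 1 point per library and a line at the group mean, WT in blue and S303/7A in orange. Hspa1b reaches 89.3 CPM in WT 2 and lies between 1.82 and 3.02 CPM in S303/7A, while Hsph1, Dnajb1 and Bag3 overlap between the genotypes.

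Marker genes of basophils and of platelets, which carry CD49b as NK cells do, were lower in S303/7A. All 13 tested basophil markers had a fold below 0, with a median log2 fold of -1.05, 1 fell over all genes and 9 fell adjusted over the list alone. All 13 tested platelet and megakaryocyte markers were below 0, with a median of -0.77, 1 fell over all genes and 11 adjusted over the list alone. Ms4a2, a chain of the IgE receptor, went from 64.9 ± 7.63 to 35.7 ± 2.69 CPM (SD, n = 3), and Vwf, von Willebrand factor, from 32.1 ± 2.06 to 13.5 ± 2.74. Both calls were lost after thinning to equal totals (adjusted p 0.0505 each in edgeR's quasi-likelihood test) and in every fit that left out 1 library. Vwf, and the uncalled platelet marker Clec1b, lie in the stretch of chromosome 6 that holds the close group of called genes described below. Their fall may therefore not bear on platelets. The lists were called by camera (adjusted p 3.4e-21 and 1.8e-19) but not with an estimated correlation (adjusted p = 0.353 and 0.201), and fry called the platelet list (0.0437) and not the basophil list (0.270). The lists share Itga2b.

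Camera also called the neutrophil list lower (8 tested, median -0.99, adjusted p 0.0237) and the cell cycle list higher (median 0.36, 33 of 36 above 0, adjusted p 6.53e-06), both lost with an estimated correlation (adjusted p = 0.80 each). The neutrophil call was also lost with fry (0.614), without the low-count filter (0.205, median -0.34), after thinning to equal totals (0.0591), without WT 2 (0.478, median -0.32) and without S303/7A 5 (0.552), and the cell cycle call with fry (0.614) and without S303/7A 6 (0.0660). In these, 0 neutrophil and 0 cell cycle genes were called, with 2 and 7 at an unadjusted p under 0.05. B cell markers differed by 0.33 ± 0.87 (SE) and T cell markers by 0.45 ± 0.41 in mean log2 CPM, S303/7A minus WT, less than 2 SE. The same held for plasma cell (0.28 ± 0.85), dendritic cell (0.05 ± 0.30), innate lymphoid (-0.23 ± 0.23), monocyte and macrophage (-0.47 ± 0.40), erythroid (-0.47 ± 0.43) and neutrophil markers (-0.92 ± 0.59). Stromal and endothelial markers, with 5 tested, differed by -1.39 ± 0.50, more than 2 SE and without overlap. That list was not called (adjusted p 0.123, camera). The monocyte and erythroid lists were not called either (0.0645 and 0.134). The first was called lower without WT 1 (0.0170), WT 3 (0.0391) and S303/7A 7 (0.00174), and the second without WT 3 (0.0177) and S303/7A 6 (0.0109). Adjusted over the list alone, 3 erythroid markers (Gata1, Klf1 and Car1) and 1 neutrophil marker (Cxcr2) were lower. In the T cell list 1 marker was higher (Trbc2), all of them named after their values were seen. No marker of the monocyte, B cell, plasma cell, dendritic cell, innate lymphoid or stromal lists passed in that way. The B and T cell lists were not called (adjusted p 0.483 and 0.117, camera) but were called higher without WT 2 (2.4e-06 and 0.00114), and the T cell list without S303/7A 5 (0.0488).

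**Figure D4:**
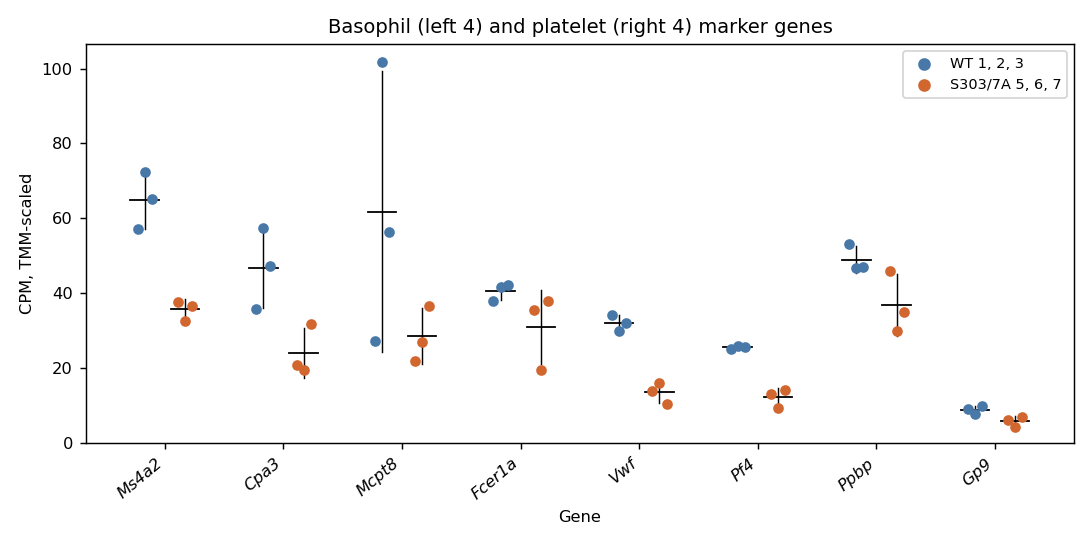
Expression of 4 basophil markers (Ms4a2, Cpa3, Mcpt8, Fcer1a) and 4 platelet markers (Vwf, Pf4, Ppbp, Gp9), in TMM-scaled CPM on the y axis, 1 point per library, with lines at the group mean and ± SD (n = 3). Ms4a2 and Vwf passed the test over all genes, and the groups overlap for Mcpt8 and do not for Pf4.

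No called gene lay near Hsf1. Within 10 Mb on each side 0 of 256 tested genes were called, against 60 of 16098 elsewhere (Fisher's exact test, 2-sided, p = 1, with 0.939 called genes expected there), and 9.77% there had an unadjusted p under 0.05 against 9.71% elsewhere. The called genes lay close to each other, in a count added after the data were seen: 38 of the 60 had another called gene within 5 Mb, against a mean of 16.3 and at most 32 in 10000 random sets (permutation p = 0.0001, the smallest they can give). Chromosome 1 held 11 and chromosome 6 held 10 of the called genes (adjusted p 0.0213 for both, Fisher's exact test over 21 chromosomes). The closest groups were on chromosome 1 from 170232749 to 173798270 (8 genes, among them Itln1, Slamf1, Slamf6 and Fcrl6), chromosome 4 from 145446740 to 148145699 (6, with Zfp979 and Zfp990), chromosome 6 from 125546774 to 129876672 (7, with Vwf, Klrb1, Klrb1c, Klrc3 and Klra17) and chromosome 8 from 82331632 to 84974834 (3, with Il15 and Mri1).

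Of the sample check lists, Gbp2b, which is known to differ between laboratory strains, had 0 counts in all WT libraries and 26, 34 and 88 counts in S303/7A 5, 6 and 7, at least 71.0-fold higher against a floor of 3 counts over the WT group. Its adjusted p over all genes was 0.0796, and it was the 1 list member called adjusted over the list alone. Nnt was at 75.1 ± 23.4 CPM in WT and 84.1 ± 15.9 CPM in S303/7A (SD, n = 3). None of 4 tested sex-linked genes and none of 12 RNA quality genes was called in edgeR's quasi-likelihood test, with 0 and 0 at an unadjusted p under 0.05.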

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

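The thinning, the surrogate variable, the heat shock level without the HSP70 pair and the neighbour distances were chosen after the data were seen. No called gene that was tested changed sign in any alternative. DESeq2 called 434 genes (154 higher, 280 lower, 343 by at least 1.5-fold), 59 of the 60 among them, and no low-count filter 171 (54 higher, 117 lower, 162 by at least 1.5-fold), all 60 among them. Limma-voom called 33 (13 higher, 20 lower, 32 by at least 1.5-fold), 31 of them shared, a threshold of 0.1 gave 94, and thinning to 43189163 counts gave 40 (13 higher), all shared, while folds of called genes moved by a median of 0.01 on the log2 scale. With 1 surrogate variable 76 were called, 55 of them shared. The cause of these shifts was not tested, except that a filter or thinning changes the counts tested. Leaving out 1 library gave 5 to 57 called genes, 1 to 38 higher, 4 to 21 lower and 5 to 57 by at least 1.5-fold, with more higher (38) than lower (19) genes without S303/7A 6. Lists called went from 4 to 0 with an estimated correlation and 1 with fry's one-way test, and from 5 to 10 without 1 library, and the heat shock list had an adjusted p from 0.0278 to 0.931 there. Neighbour counts were 23 at 1 Mb and 25 at 2 Mb, and windows of 5 and 20 Mb around Hsf1 held 0 called genes. Of 29 called named genes, thinning kept 22, limma-voom 20, library totals 28 and the others in full, and leaving out 1 library kept between 3 and 15. At less depth fewer genes passed, as the thinning shows. The simulation, with these depths and 3 libraries per group, did not vary depth. It recovered 20 of 50 genes changed 2-fold, which were not drawn from those of lowest mean CPM.

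Directions that turned were of uncalled results, and the cause was not tested. Eomes had a log2 fold of -0.38 with limma-voom and -0.19 with the surrogate variable, and from -0.97 to 0.58 without 1 library. Gzma had 0.028 with limma-voom and from -0.19 to 0.15 without 1 library, and Bag3 from -0.036 to 0.18. Adjusted p of lists that turned were as follows. With library totals it was 0.969 for the chaperonin and 0.917 for the unfolded protein response lists. With the strict filter it was 0.985 for chaperonin, 0.787 for unfolded protein response and 0.919 for dendritic cell markers. It was 0.712 for plasma cell markers with no filter. With fry it was 0.957 for unfolded protein response and 0.989 for dendritic cells, and after thinning 0.980 and 0.954. Without 1 library the ranges were 2.4e-06 to 0.786 for B cells, 0.511 to 0.885 for NK transcription factors, 0.269 to 0.960 for activating receptors, 0.565 to 0.993 for cytokine receptors, 0.521 to 0.916 for chaperonin, 0.0660 to 0.849 for ribosomal proteins, 0.668 to 0.939 for dendritic cells, 0.565 to 0.963 for unfolded protein response, 0.559 to 0.939 for glycolysis, 0.0163 to 0.926 for interferon-stimulated genes, 0.258 to 0.816 for oxidative phosphorylation, 0.737 to 0.968 for oxidative stress, 0.30 to 0.996 for plasma cells, 0.386 to 0.963 for proteasome and 0.119 to 0.937 for translation factors.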

Other observations

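The tests of other splits, of positions and blocks and of basophil and platelet markers were chosen after their results were seen; those of near-identical copies, GC content and length were not, though WT 3 and S303/7A 7 were picked for the last pair from the pattern itself. Ccl6 and Ccl9, chemokine genes also chosen after their values were seen, fell from 460 ± 89.5 to 212 ± 16.8 CPM and from 159 ± 35.4 to 71.1 ± 3.91 CPM (SD, n = 3, adjusted p 0.0439 and 0.0462 in edgeR's quasi-likelihood test). After thinning to equal totals Ccl6 kept its call (0.0356, same test) and Ccl9 lost it (0.0505). The immediate early list had a median log2 fold of -0.23 and the NF-kB list -0.19, neither called (adjusted p 0.0645 and 0.0591, camera), though each was called lower in several alternatives, among them without WT 3 (0.0177 and 1.5e-06) and without S303/7A 7 (0.0181 and 0.0132). Interferon-stimulated genes (35 tested, median -0.06), ribosomal proteins (57 tested, -0.04), proteasome subunits (31 tested, 0.04) and glycolysis (23 tested, 0.01) were not called. Of glycolysis genes Hk2 fell, and adjusted over the list alone 2 rose (Eno1 and Gapdh, named after their values were seen) and 1 fell (Hk2). Eno1 and Gapdh each have a near-identical copy that fell. Eno1b had a log2 fold of -1.37 against 0.34 for Eno1. Gm13394, which shares 99.9% of 1000 bases with Gapdh, had -0.98 against 0.26 for Gapdh. How reads were divided between copies is not known, so these 2 rises are uncertain.

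Pseudogenes were more frequent among the called genes, 16 of 60 against 1361 of 16480 tested (odds ratio 4.08, Fisher's exact test, 2-sided, p = 1.95e-05). Ifi206, with the widest spread within genotypes among 5857 genes with mean log2 CPM of at least 5, was at 91.3, 7.24 and 5.16 CPM in WT 1, 2 and 3 and at 180, 161 and 154 CPM in S303/7A, and was chosen after its values were seen.

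The real split gave 60 called genes (22 higher, 38 lower, 58 by at least 1.5-fold) and the highest of the other 9 splits gave 0, so 1 of 10 splits reached each count. With 10 splits the share cannot go below 0.1. For gene lists the real split gave 4 calls and the highest other 15, and all 10 splits gave at least as many. A structure among the libraries and a preset correlation of 0.01 that is too low (estimates reached 0.816, for B cell markers) would both raise such counts and were not separated.

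The called genes clustered in the genome. DNA carried along with the Hsf1 allele is not where they lie, with 0 called genes within 10 Mb of it (upper exact limit 5.96% of the called genes). Copies of other genes do not account for most protein-coding calls, since 23.3% of 43 had one. Copies were still more frequent there than among 600 random protein-coding genes, of which 11.3% had one (Fisher's exact test, 2-sided, p = 0.0289). For pseudogenes the question stays open, since 71.4% of 14 had one, above the 50% set in advance, and so did 71.5% of 600 random pseudogenes. A candidate explanation is blocks of another strain background. Among uncalled genes inside the 4 closest groups 31.0% had an unadjusted p under 0.05 against 9.10% outside (Fisher's exact test, 2-sided, p = 9.43e-19). The groups were drawn around called genes of the same fit, and neighbouring genes are not independent. That p-value does not weigh strain blocks against other reasons for linked changes. Of 5 tested genes known to differ between strains only Gbp2b, with 0 counts in all WT libraries, passed adjusted over the list alone. It lies on chromosome 3, outside these groups, so it may bear on strain background but not on these blocks. The levels of the others cannot decide, since the strains that might be involved are not known here. Of the 60 genes of lowest p in each of the other 9 splits, which mix the genotypes unevenly, 7 to 19 had a neighbour within 5 Mb in all but 1 split. That split set WT 1, S303/7A 5 and S303/7A 7 against WT 2, WT 3 and S303/7A 6, and had 31. The real split had 38 and the random mean was 16.3. Called neighbours within 5 Mb also lay outside the 4 closest groups. Among them were Lgals3 and Supt16, Kcnj8 and Bhlhe41, and Pik3ip1 and Nudcd3, chosen after their values were seen. Random sets hold such neighbours too, so a single pair cannot show linkage. An effect of the HSF1 mutations on the called genes, in these groups or in such pairs, was not tested.

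Basophil and platelet markers were lower in S303/7A together, with 100% of the tested markers of both lists below 0, though both list calls were lost with an estimated correlation (adjusted p = 0.353 and 0.201). A lower share of these CD49b-positive cells among the sorted cells may lie behind it and stays untested, since that percentage is the pattern itself. The sort took CD49b-positive cells and would not remove them, and the most abundant basophil markers in WT, chosen after their values were seen, were Hdc, at 137 CPM there and 61.2 CPM in S303/7A, and Itga2b, which platelets share, at 115 and 55.4 CPM. Against a purer sort from every other cell type, 4 of 9 lists of other types lay above basophil markers by more than 2 SE on the log2 scale, T cell (1.42 ± 0.40, SE), dendritic cell (1.02 ± 0.31), innate lymphoid (0.74 ± 0.26) and monocyte markers (0.49 ± 0.19), while B cell markers, tried first (1.29 ± 0.74), plasma cell (1.25 ± 0.80), erythroid (0.50 ± 0.53), neutrophil (0.04 ± 0.63) and stromal markers (-0.42 ± 0.36) did not. Such a sort cannot be told apart from a lower share of basophils and platelets, because those 4 lists hold genes abundant in these sorted cells (Trbc1 at 311, Cst3 at 100.2, Gata3 at 228 and Ccr2 at 676 CPM in WT, chosen after their values were seen), which could hide a fall, and whether the mice or the gates differed was not tested.

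Many genes differed more between libraries of one genotype than between genotypes, and the deviations ran together across the genotypes. Across 5857 genes, which are not independent replicates, the deviations from the genotype mean of WT 3 and S303/7A 7 had r = -0.586 and those of WT 1 and S303/7A 7 r = 0.575, while S303/7A 6 had r = 0.538 with WT 3 and -0.498 with WT 1. Deviations within a genotype cancel out for each gene, so these values are tied to each other and are not separate agreements. Of the 50 genes with the widest spread, 49 had their lowest WT value in WT 3 and their highest S303/7A value in S303/7A 7, Eomes, Hnrnpab and Pink1 among genes of this kind, the last 2 chosen after their values were seen. Transcript length is not the trend behind it in that pair of libraries (Spearman's rho -0.0899 in S303/7A 7 and -0.02 in WT 3, with 0.203 in S303/7A 5 the largest), while GC content, with rho 0.297 in S303/7A 7, -0.129 in WT 3, -0.025 in WT 1, 0.198 in WT 2, -0.12 in S303/7A 5 and -0.190 in S303/7A 6, did not reach the size of 0.3 set in advance for the first pair and was not under 0.1 in both, so it stays open. Library batches that cross the genotypes stay open too, untested since the labels give none, and no biological explanation was tested.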
